A study of Mus musculus with 2 samples.

How the data were processed

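Messenger RNA was measured in 2 cultures of primary mouse chondrocytes, 1 treated with a control hairpin and 1 with a hairpin against Gpx4. Groups were taken from the treatment recorded in the labels, which say nothing of separate animals or cultures within a group. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, and libraries were made with a stranded mRNA kit.

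The authors deposited 1 table per library. Per the submitters' processing notes, Trimmomatic, HISAT2 and Cufflinks were used with the mouse build GRCm38, without versions or the order and settings of the steps. The deposited values were read as FPKM, reads scaled by gene length and by library total, from the values themselves and from Cufflinks in those notes, since the file headers name only the sample. The setting for strand when reads were assigned to genes, and any filter, are not given in the sources used here. Overlapping and antisense genes and near-identical gene copies may therefore share reads. The gene identifiers are RefSeq's, and 27 symbols that had been turned into dates were restored through their Entrez gene numbers.

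The depth was worked out from the FPKM values. The ratio between the libraries of genes with few reads takes fixed steps, which give library totals of 19729142 for shNC and 21313211 for shGpx4. With these totals, the values of all 15153 genes above 0 in either library divided out as whole reads over a whole length, within 6.4e-10 of a whole number. The reads obtained are the smallest whole numbers that give both values, and the true reads are these or a common multiple of them. They sum to 89.9% of the total in shNC and 90.0% in shGpx4. Exact Clopper-Pearson 95% intervals of the ratio were computed from these reads, so they are as wide as or wider than those of the true reads. They cover counting error only, and reads of a PCR-amplified library are not independent molecules. A level of 0 was set beside the FPKM that 3 reads would give. Of the 21878 genes, 6725 were at 0 in both libraries.

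Ratios were log2 of (FPKM + 1) in shGpx4 over (FPKM + 1) in shNC without further rescaling. Genes with a mean FPKM of at least 1 over both libraries were called measured. With 1 library per group no test, standard error or p-value was computed. Genes were counted by size, at least 2-fold, and list members at least 1.5-fold. Before the data were examined, 37 gene lists with 799 entries were fixed, of which 782 matched the tables. The unmatched ones were Mx1, Mx2, 2 haemoglobin genes and the 13 mitochondrially encoded genes, which are not analysed here. For each list with at least 5 measured members, the median was placed among 10000 random lists of the same size, drawn from 20 bins of mean FPKM, as a description of these libraries. A list was said to stand apart at or below percentile 2.5 or at or above 97.5. No term database was used.

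The genes named were fixed by rule before the data were examined. They were Gpx4, the 10 highest and 10 lowest ratios among genes with a mean FPKM of at least 5 (predicted genes, pseudogenes and small RNA genes left out), up to 4 measured members of each described list with the largest absolute ratio, and Col2a1, Acan, Sox9, Mmp13, Mmp3, Adamts5, Slc7a11, Acsl4, Tfrc, Ptgs2 and Hmox1. Some genes that this rule takes are not reported here. Cst3, Cxcl12, Dlx5, Ndrg1, Bnip3l, Matn1, Epyc, Col9a1, Tnfaip3, Nfkbia and the Y-linked genes were named after their values were seen. Another 10 lists were also chosen after the values were seen and appear only in the closing section, apart from the Y-linked genes.

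Alternatives fixed beforehand were a pseudocount of 0.1, centring on the median, rescaling by the 75th percentile or by a trimmed mean of log ratios (30% of ratios and 5% of mean levels trimmed at each end), rescaling to a common sum of FPKM (a TPM-like scale), a minimum mean of 5, no filter, and lists without genes shared with another list. Added after seeing the data were ratios of the recovered reads with 0.5 reads added, and random lists matched on mean FPKM and transcript length from GENCODE vM21.

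The computation was tested on simulated data made from these 21878 genes and both library totals, with 200 genes changed. The totals were recovered exactly, 95% of the 3-fold and 100% of the 5-fold changed genes passed the 2-fold rule, and 0 of 10804 unchanged measured genes did. Of 20 lists of 20 genes shifted by 0.2, 20 were found, and 1 of 20 unshifted lists lay outside. The simulation holds counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Locations come from the RefSeq annotation of GRCm38.p6.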

Results

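Primary chondrocytes, the cells that make and maintain cartilage, were taken from C57BL/6 mice, grown in culture and treated with lentivirus carrying a short hairpin RNA. One culture received a control hairpin (shNC) and the other a hairpin against Gpx4 (shGpx4). Gpx4 encodes glutathione peroxidase 4, a selenoprotein that reduces lipid hydroperoxides and restrains ferroptosis, an iron-dependent form of cell death. Poly(A) RNA of each culture was sequenced, which gave 2 libraries with 1 library per group. The library totals behind the deposited FPKM values were 19729142 reads for shNC and 21313211 reads for shGpx4, and 10997 of the 21878 genes listed had a mean FPKM of at least 1 and are called measured. No value has a replicate, so no difference was tested, and each one describes these 2 libraries. Ratios are log2 of (FPKM + 1) in shGpx4 over (FPKM + 1) in shNC, a scale that understates differences of weakly expressed genes. Intervals are exact 95% intervals of the FPKM ratio itself, in log2, and cover counting error only, not the spread between cultures.

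Gpx4 was lower in the library that carried the hairpin against it. Its level was 161 FPKM in shNC and 96.2 FPKM in shGpx4, a log2 ratio of -0.73 with a counting interval of -0.81 to -0.67. The remaining level was 59.9% of that in shNC, with a counting interval of 56.9% to 63.0%, from at least 3934 and 2545 reads. Of the 10997 measured genes, 130 had a lower ratio than Gpx4. In the RefSeq annotation of GRCm38.p6 the gene lies on chromosome 10 from 80047166 to 80056439. Among its neighbours, Sbno2, separated from it by 552 bases, was higher in shGpx4 (22.5 against 35.5 FPKM, log2 ratio 0.63), while Polr2e was slightly lower (57.6 against 48.5 FPKM, -0.24). The median ratio of the 7 measured neighbours was -0.05, at percentile 49.99 of random lists matched on mean FPKM.

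The stated purpose of the series was to learn how GPX4 acts, by sequencing RNA with and without its knockdown. By a size rule of at least 2-fold, 112 genes were higher and 58 were lower in the shGpx4 library, and by at least 1.5-fold 329 were higher and 216 lower. The counting interval lay above 0 for 111 of the 112 and below 0 for all 58. Among all 10997 measured genes it excluded 0 for 4987, or 45.3%, so excluding 0 was common at this depth. The counts depend on how low values are treated: with a pseudocount of 0.1 they were 194 and 97, and among genes with a mean of at least 5 they were 60 and 37. The median ratio over all measured genes was -0.04.

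Sema7a, a membrane-anchored semaphorin, was the highest of the named genes, at 3.29 FPKM in shNC and 27.2 FPKM in shGpx4 (log2 ratio 2.72). Col2a1, the collagen of hyaline cartilage, followed with 8.96 and 58.4 FPKM (2.58), and Chl1, a neural adhesion molecule, with 11.0 and 64.2 FPKM (2.44). The prostaglandin transporter Slco2a1 (2.09), the epithelial cytokine Tslp (2.08), the aggrecan-cleaving protease Adamts1 (1.86) and the insulin-like growth factor binding protein Igfbp5 (1.59) were also higher in shGpx4. Bst1 (1.65), D17H6S56E-5 (1.63) and Klra4 (1.67) completed the 10 highest. Klra4 belongs to a family of closely related receptor genes among which reads can be shared, so its value is uncertain. At the other end Sfrp2, a secreted modulator of WNT signalling, was at 56.4 FPKM in shNC and 2.89 FPKM in shGpx4 (-3.88). Itgbl1 was at 47.1 and 7.09 FPKM (-2.57), and Aspn, the small leucine-rich proteoglycan asporin, at 189 and 46.1 FPKM (-2.02). Myoc (-2.12), Gc (-2.04), Sparcl1 (-1.99), Pcp4l1 (-1.85), Angptl7 (-1.81), Smoc2 (-1.71) and Nov (-1.62) were lower as well.

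**Figure D1:**
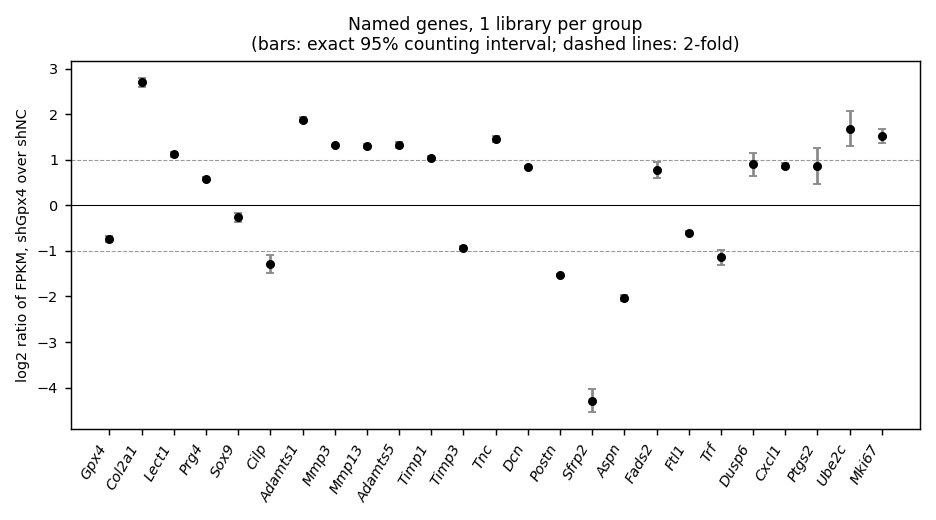
Log2 ratio of FPKM, shGpx4 over shNC and without a pseudocount, for Gpx4 and other named genes, where points are the ratio of 1 library per group, bars are exact 95% counting intervals and dashed lines mark 2-fold. Col2a1 lies above 2-fold, Sfrp2 and Aspn lie below it, and Gpx4 lies between 0 and 2-fold lower.

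Genes of cartilage matrix and chondrocyte identity went both ways. Of 29 members 15 were measured, of which 2 were at least 1.5-fold higher, 1 was at least 1.5-fold lower and 12 lay between. Col2a1 had the largest ratio, and Lect1, which encodes the cartilage protein chondromodulin, was at 124 FPKM in shNC and 270 FPKM in shGpx4 (1.12). Cilp, a matrix protein of the middle zone of articular cartilage, was at 9.07 and 3.72 FPKM (-1.09), and the lubricin gene Prg4 at 135 and 203 FPKM (0.58). The chondrocyte transcription factor Sox9 was slightly lower (21.8 against 18.2 FPKM, -0.25). Acan, which encodes aggrecan, was listed at 0 in shNC, where 3 reads would give at most 0.020 FPKM, and at 0.006 FPKM in shGpx4. Matn1 and Epyc were listed at 0 in both libraries, and Col9a1, at 0.024 and 0.011 FPKM, was also among the members under the filter. These cartilage transcripts were thus at or near 0 in both libraries, while Col2a1 and Lect1 were present. The name chondrocyte is that of the labels, and the identity of the cells was not tested. The list median was 0.17, at percentile 99.96 of 10000 random lists matched on mean FPKM, but this call rests on the filter: over 26 members with no filter on low values the median was -0.06, at percentile 7.31. Hypertrophic chondrocyte genes did not stand apart, with a median of -0.12 over 9 members at percentile 18.6, which turned to 0.03 over the 5 members with a mean of at least 5. In that list Ibsp (-0.63), Mef2c (-0.49) and Enpp1 (-0.44) were lower, and the collagenase gene Mmp13 was higher.

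Proteases that break down cartilage matrix were among the genes with larger ratios. The stromelysin gene Mmp3 was at 5144 FPKM in shNC and 12910 FPKM in shGpx4 (1.33), Mmp13 at 102 and 252 FPKM (1.30), and the aggrecanase gene Adamts5 at 17.9 and 44.8 FPKM (1.28). Mmp12 was at 0.242 and 2.55 FPKM (1.51). Of 22 measured matrix-degrading enzymes, 5 were at least 1.5-fold higher and 2 were at least 1.5-fold lower, the latter being Mmp11 (-0.84) and Ctsk (-0.63). The list median of 0.09 stood at percentile 99.5, a call that also rests on the filter, since with no filter on low values the median was -0.01 at percentile 69.8. Inhibitors of these enzymes were split: Serpina3n (169 against 479 FPKM) and Timp1 (1.05) were among those higher, and Timp3 (-0.92) and Cst3 (-0.59) were lower. Their median of -0.12 over 8 members stood at percentile 30.7.

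Fibroblast and dedifferentiation genes had a median of 0.22 over 20 members, above all 10000 random lists. Tenascin C (Tnc) was at 15.8 FPKM in shNC and 43.5 FPKM in shGpx4 (1.41), decorin (Dcn) at 2808 and 5042 FPKM (0.84) and Thy1 at 18.7 and 28.6 FPKM (0.59), whereas periostin (Postn) was at 948 and 327 FPKM (-1.53). Synovial and tendon markers had a median of 0.53 over 7 members, also above all 10000 random lists, with Thbs4 (1.18), Pdpn (0.61) and Prg4 higher and Clec3b lower (-1.56). With no filter on low values this median was 0.16 over 10 members at percentile 99.4. Osteoblast markers stood at the low end, with a median of -0.28 over 8 members at percentile 0.370. In this list the osteocyte genes Dmp1 (12.6 against 3.81 FPKM) and Phex (-0.66) were lower, as were Omd (-1.61) and Ibsp, while the other 4 measured members had ratios above 0, Dlx5 (0.24) the highest of them. With no filter on low values the osteoblast median was -0.04 at percentile 35.8, and over the 5 members in no other list it was -0.66. Adipocyte markers had a median of -0.20 over 5 members at percentile 8.28, led by Lpl (-0.58). With no filter, that median was -0.21 at percentile 0.280.

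Markers of blood and vascular cells were few. Of 19 macrophage and leukocyte markers 4 were measured, with Lyz2 at 7.67 FPKM in shNC and 1.86 FPKM in shGpx4, H2-Ab1 at 11.1 and 5.35 FPKM, Cd14 at 9.19 and 17.1 FPKM and Cd68 at 3.90 and 3.80 FPKM. Of 10 osteoclast markers 3 were measured, namely Ctsk, Acp5 (0.23) and Nfatc1 (0.08). Of 15 endothelial and perivascular markers 4 were measured, with Eng at 3.22 and 6.67 FPKM (0.86). No skeletal muscle or erythroid marker reached a mean of 1 FPKM.

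Genes that act for or against ferroptosis did not stand apart as groups. The defence list had a median of 0.03 over 20 members at percentile 92.1, or -0.02 over the 13 in no other list, and the list of ferroptosis-promoting and iron uptake genes had a median of -0.05 over 20 members at percentile 35.9. Within the defence list the desaturase gene Fads2 (0.76) and Gch1, the first enzyme of tetrahydrobiopterin synthesis (0.74), were higher. The ferritin light chain gene Ftl1 was lower, at 2312 FPKM in shNC and 1530 FPKM in shGpx4 (-0.60). Slc7a11, which encodes the cystine transporter, had a mean under 1 FPKM and so was not counted as measured, but it was higher in shGpx4, at 0.238 and 0.466 FPKM. Its log2 ratio without the pseudocount was 0.97, with a counting interval of 0.44 to 1.51 from at least 45 and 95 reads. In the promoting list the transferrin gene Trf was lower, at 21.5 and 9.74 FPKM (-1.07). Ptgs2, often read as a ferroptosis marker, was at 4.55 and 8.26 FPKM (0.74), and Acsl4, which loads polyunsaturated fatty acids into phospholipids, at 12.5 and 17.8 FPKM (0.48). The transferrin receptor gene Tfrc differed by less than its counting error (-0.04, interval -0.18 to 0.09), and Hmox1 was at 446 and 413 FPKM (-0.11).

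Antioxidant genes differed little as groups. NRF2 targets had a median of 0.00 over 27 members at percentile 83.8, with Gsta4 (-0.59), Gstm1 (-0.51) and Aldh3a1 (-0.51) lower and Txnrd1 (0.33) higher. Selenoproteins other than Gpx4 had a median of -0.12 over 20 members at percentile 7.89, and among the 18 with a mean of at least 5 FPKM it was -0.15 at percentile 1.94. In this list the deiodinase gene Dio2 was higher (26.3 against 58.2 FPKM, 1.12), as was the secreted peroxidase gene Gpx3 (0.57), while Selm (-0.42) and 2700094K13Rik (-0.51) were lower. Other peroxidases and superoxide dismutases had a median of -0.05 over 18 members at percentile 55.6, with Sod3 (0.62) higher and Gpx1 (-0.41) lower.

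Cell division genes made up the list farthest from 0. Of 25 measured mitosis genes, 22 were at least 1.5-fold higher in the shGpx4 library and none was lower, and the median of 0.96 lay above all 10000 random lists. Ccnb2 was at 3.09 FPKM in shNC and 9.86 FPKM in shGpx4 (1.41), Ube2c had a ratio of 1.47, and the proliferation marker Mki67 was at 2.11 and 6.07 FPKM (1.19) and Kif20a at 3.44 and 8.73 FPKM (1.13). DNA replication and S phase genes had a smaller median of 0.21 over 24 members, again above all 10000 random lists, with Ccne1 (0.95), Rrm2 (0.92), Mcm5 (0.79) and Uhrf1 (0.62) at the top. Among the 12 with a mean of at least 5 that median was 0.14. The 4 measured Y-linked genes, chosen after their values were seen, were lower in the same library, among them Ddx3y at 15.9 and 6.67 FPKM (-1.14).

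The MAPK and NF-kB lists were higher as groups. The MAPK immediate early and feedback list had a median of 0.33 with 26 of 28 members above 0, beyond all 10000 random lists, and Dusp2 (0.85), Dusp6 (0.75), Etv4 (0.72) and Phlda1 (0.64) led it. NF-kB targets and inflammatory genes had a median of 0.12 over 29 members at percentile 99.97, with 20 members above 0 and 9 below. Cxcl1 was at 174 FPKM in shNC and 319 FPKM in shGpx4 (0.87), Lif at 0.419 and 1.79 FPKM (0.97) and Tnfaip2 at 52.5 and 100.1 FPKM (0.92). Il6 was at 0.311 and 2.01 FPKM, with a counting interval of -0.26 to 8.19 that holds 0. That interval comes from the smallest reads that give these values, 1 and 7. A multiple of these reads would narrow it, so these smallest reads alone do not settle whether the Il6 ratio exceeds counting error. The chemokine gene Cxcl12 (-0.73) and the feedback inhibitors Tnfaip3 (-0.31) and Nfkbia (-0.30) were lower, with counting intervals below 0. Interferon-stimulated genes were lower as a group, with a median of -0.17 over 33 members at percentile 0.070, and Psmb9 (-1.13), Psmb8 (-0.59), Isg15 (-0.56) and Ifit3 (-0.51) were the farthest from 0.

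The lipid synthesis lists and the hypoxia and glycolysis list were higher as well. Cholesterol biosynthesis had a median of 0.13 over 24 members at percentile 99.98, and Stard4 (0.48) was among its higher members. Fatty acid synthesis and desaturation had a median of 0.18 over 20 members, beyond all 10000 random lists, with Fads2, Acaca (0.59), Acsl4 and Scd1 (0.38) leading. Over the 14 members in no other list it was 0.12. Hypoxia and glycolysis had a median of 0.15 over 26 members, beyond all 10000 random lists, with Hk2 (0.49), Pgk1 (0.49) and Ldha (0.47) higher. With no filter it was 0.10 over 28 members. Of the 26 measured members 10 had ratios below 0, among them the hypoxia-response genes Ndrg1 (-0.44, interval -0.49 to -0.40) and Bnip3l (-0.22, interval -0.29 to -0.16). The hypoxia marker Car9 was at -0.60, with a counting interval of -1.80 to 0.43 that holds 0. That interval comes from the smallest reads that give its values, and a multiple of them would narrow it.

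Ribosomal protein genes were lower without exception. All 30 had a ratio below 0, the median was -0.29, below all 10000 random lists, and Rps14 (-0.70), Rps18 (-0.51), Rps23 (-0.50) and Rpl5 (-0.38) were the lowest. Ribosomal protein genes have many processed pseudogene copies, among which reads can be shared. Housekeeping reference genes had a median of 0.05 over 16 members at percentile 94.0, within which Pgk1 was higher and B2m lower (-0.47).

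Stress and growth factor lists lay inside the range of random lists. The integrated stress and unfolded protein response list had a median of -0.06 over 27 members at percentile 37.9, although Atf5 (-0.81), Mthfd2 (-0.67), Ddit3 (-0.60) and Trib3 (-0.60) were each lower. The p53 targets had a median of -0.06 at percentile 37.4, with Rrm2b (-0.43) lower and Btg2 (0.36) higher. Apoptosis and necroptosis genes had a median of 0.02 at percentile 89.7, with Ripk3 (0.51) and Bcl2 (0.46) higher. Autophagy and lysosome genes had a median of -0.04 at percentile 59.8, and nuclear-encoded oxidative phosphorylation genes -0.03 at percentile 62.2. TGF-beta targets had a median of 0.00 at percentile 83.6, with Acta2 (-0.88) and Pmepa1 (-0.71) lower. The WNT list had a median of 0.08 over 14 members at percentile 96.7, but -0.17 at percentile 15.3 over the 5 with a mean of at least 5. In it Sfrp2 was lower and Sfrp1 was at 0.407 and 4.29 FPKM (1.91).

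**Figure D2:**
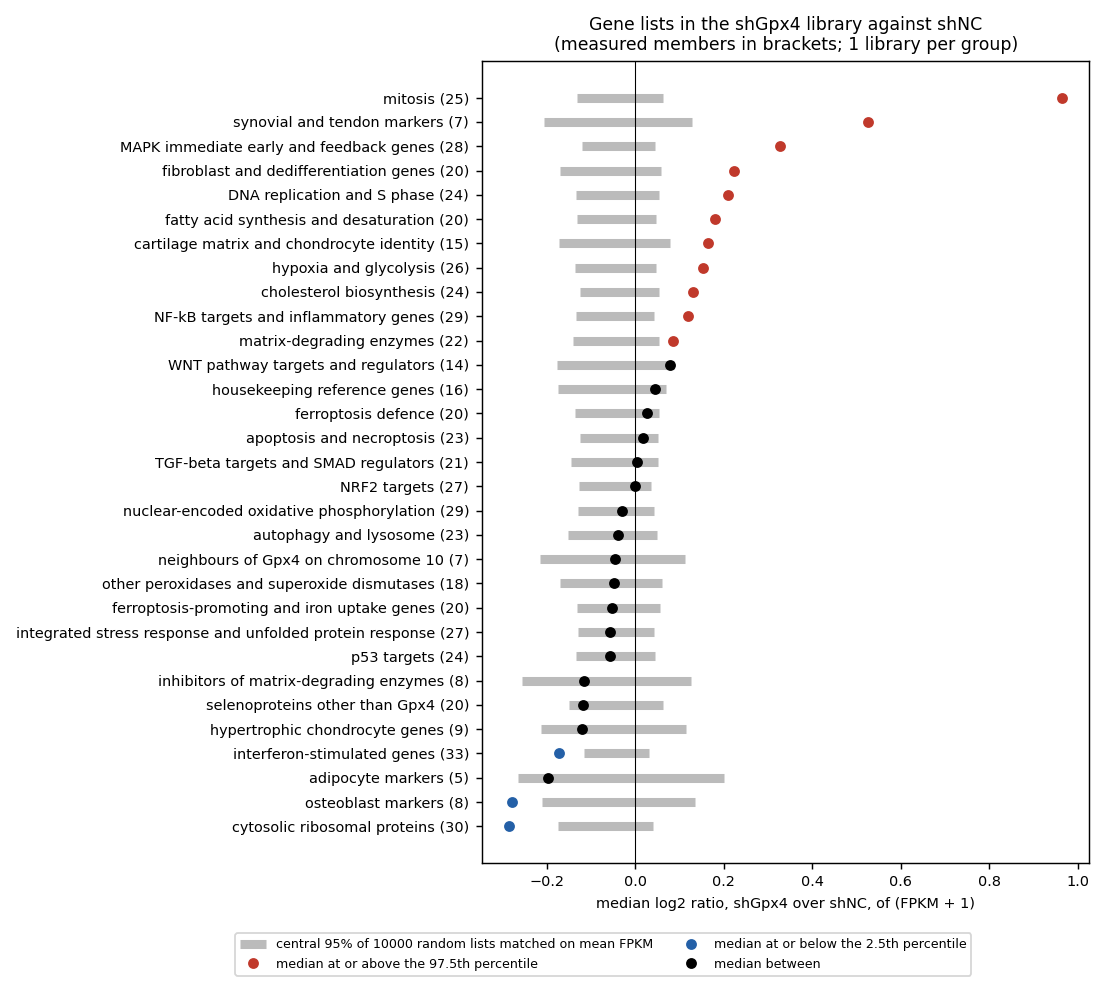
Median log2 ratio of (FPKM + 1), shGpx4 over shNC, for the 31 gene lists with at least 5 measured members, with grey bars for the central 95% of 10000 random lists matched on mean FPKM. The mitosis list lies farthest above 0 and the cytosolic ribosomal protein list farthest below it.

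Of 31 lists with a percentile, 11 stood apart at the high end and 3 at the low end. Random lists would put 1.55 outside the limits at both ends together, but genes of a real list vary together more than random genes do, so more would lie outside by chance.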

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

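The alternatives with recovered reads and with length-matched random lists were chosen after seeing the data. Over 35 results and 337 alternative values, 316 stayed on the same side of the threshold or, for values with no threshold, within counting error or 1.5 times, those of Gpx4 among them. Of the 316, 11 list medians took the other sign, in 8 lists that did not stand apart. Among these were hypertrophic and WNT genes with a mean of at least 5, and ferroptosis defence and TGF-beta targets without shared genes. The others were apoptosis genes on the TPM-like scale, and NRF2 targets, autophagy and oxidative phosphorylation genes after centring or rescaling. Centring moves list and random genes by the same amount, so list percentiles could not change under it. Rescaling by the 75th percentile or the trimmed mean, with factors of 0.98 and 0.97, acts almost the same way. The 316 thus include values that could hardly have changed. The counts of genes at least 2-fold higher and lower, 112 and 58, became 194 and 97 with a pseudocount of 0.1, 60 and 37 with a mean of at least 5, 204 and 104 on the TPM-like scale, and 203 and 104 from recovered reads with 0.5 reads added. A pseudocount of 0.1 and the added reads shrink low genes less, the TPM-like scale does so and also lets more genes past the minimum, and a mean of at least 5 counts fewer genes. The median of all measured genes, -0.039, was -0.044 with a pseudocount of 0.1, 0 by construction when centred, -0.013 after the 75th percentile, -0.00038 after the trimmed mean, -0.022 with no filter and -0.043 on the TPM-like scale. With no filter on low values the cartilage list median reversed to -0.064 and the matrix-degrading list median to -0.0093, and the osteoblast median weakened to -0.039, while the adipocyte median moved outside the random range at -0.21. On the TPM-like scale the cartilage and matrix-degrading medians weakened to 0.012 and 0.011. Selenoproteins stood apart at -0.15 with a mean of at least 5. These settings add or remove weakly expressed members, and the cause was not tested further. No paired analysis was possible because each group has 1 library. Intervals are wide for genes with few recovered reads, such as Il6, and for every gene the recovered reads are only the smallest whole numbers.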

Other observations

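All lists and tests in this part were chosen after the values were seen, apart from the mitosis list itself. Genes of the acute-phase response, which IL-6 family cytokines drive through STAT3, were higher in the shGpx4 library as a group, by unequal amounts. Of 25 measured members of such a list, 24 had a ratio above 0 and 14 were at least 1.5-fold higher, with a median of 0.63. Among the members with larger ratios, the metallothionein gene Mt2 was at 208 FPKM in shNC and 629 FPKM in shGpx4. Steap4 was at 187 and 508 FPKM, and Socs3, a feedback inhibitor of the pathway, at 12.6 and 33.2 FPKM. The acute-phase protein genes Saa3 (0.12) and Hp (0.12) differed little, as did Bcl6 (-0.02), while Serpina3n was at 169 and 479 FPKM. Whether STAT3 signalling differed between the cultures was not tested. Sbno2, the neighbour of Gpx4, is in this list too, and other members were already in lists described above. Among them are Bcl3, Il6, Lif, Lcn2 and Saa3 (NF-kB), Junb (MAPK), and Timp1 and Serpina3n (inhibitors of matrix-degrading enzymes). The result thus partly repeats those lists, and the list was chosen with the values known. Il6 itself was at 0.311 and 2.01 FPKM. Its counting interval of -0.26 to 8.19, from the smallest reads that give these values, holds 0, and a multiple of those reads would narrow it.

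Genes of MHC class I antigen presentation were lower, with 17 of 19 measured members below 0 and a median of -0.41. B2m, Tap1, Psmb8 and Psmb9 are also in the interferon-stimulated list, so this result and that one overlap. H2-D1 was at 1436 FPKM in shNC and 990.2 FPKM in shGpx4, H2-K1 at 828 and 554 FPKM, and H2-Q7, whose reads can be shared with its near-identical neighbours, at 15.8 and 6.63 FPKM. Small leucine-rich proteoglycans parted, with a median of -0.20 over 11 members at percentile 4.60 of random lists. Ogn was at 2568 and 1084 FPKM (-1.24), and its neighbours on chromosome 13, Aspn, Omd and Ecm2 (-0.83), were lower as well, while Prelp was at 468 and 638 FPKM (0.44) and Podn at 2.86 and 6.22 FPKM (0.90).

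The 4 measured Y-linked genes were lower in the shGpx4 library. Without the pseudocount, their log2 ratios were -1.25 for Ddx3y, -1.09 for Eif2s3y, -1.37 for Kdm5d and -1.26 for Uty. Counting error is argued against, since the highest upper bound of their log2 FPKM ratios was -0.89. A candidate explanation is a smaller share of cells with a Y chromosome in the shGpx4 culture, whether from animals of the other sex or from loss of the chromosome. In that case 1 common ratio should hold for all 4 genes. The common value of -1.23, or 42.7% of the shNC level, lay inside each of the 4 counting intervals. That value came from the summed reads of these same genes, and the intervals may be wider than those of the true reads. The match is therefore weak support. An effect of the knockdown on these transcripts cannot be told apart from a smaller share of such cells with 1 library per group. The 5 X-linked partner genes all had ratios and counting intervals above 0. Their median with the pseudocount was 0.17, at percentile 98.7 of random lists. Whether these values bear on the sex of the animals was not tested.

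The mitosis genes were higher in the shGpx4 library. Counting error in genes with few reads is argued against, because the counting interval lay above 0 for 25 of the 25 genes. A difference of scale between the libraries is argued against as well, because the scales were close. The factors, shGpx4 over shNC, were 0.98 by the 75th percentile and 0.97 by the trimmed mean, and the lowest median over the rescalings was 0.99. A difference in growth state between the 2 cultures that the knockdown did not bring about, such as density at harvest, cannot be told apart from an effect of the knockdown, since there was 1 library per group.

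The Hox B genes, which carry positional identity along the body axis, were higher in the shGpx4 library, though weakly expressed. Of 10 genes 8 had reads and 2 reached a mean of 1 FPKM, Hoxb7 at 1.68 FPKM in shNC and 7.84 FPKM in shGpx4 and Hoxb6 at 0.627 and 2.29 FPKM, while Hoxb2 rested on at least 5 reads in shNC. Counting error is argued against, because the counting interval lay above 0 for 8 of the 8 genes with reads. The 3 distal Hox A genes Hoxa10, Hoxa11 and Hoxa13 had intervals below 0, Hoxa13 at 3.99 and 0.609 FPKM. The Hox A list had a median of -0.22 over 8 measured members at percentile 1.73, the Hox C list 0.12 over 7 at percentile 95.6, and the Hox D list -0.10 over 4. Cells from other skeletal sites or animals in the shGpx4 culture may give such a split, but this cannot be told apart from an effect of the knockdown with 1 library per group. Together with the Y-linked values it leaves open that the cultures differed in origin as well as in hairpin, which bears on every comparison between them.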
